A study of Arabidopsis thaliana with 18 samples.

How the data were processed

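RNA from whole Arabidopsis thaliana seedlings was sequenced by the submitters, who name 18 samples in 6 groups: wild-type Col-0 (WT) and the mutant stch4-1, each at 0, 4 and 24 h of cold, with 3 samples per group. Seedlings were 14 days old and cold was 4 °C, per the labels, except that the treatment tag of the 24 h samples reads 24 °C for 4 h, against their titles and descriptions. The table used here holds 6 libraries, those of WT and stch4-1 at 4 h. The other 12 samples, taken at 0 h and 24 h, were not analysed here. The comparison of the genotypes at 4 h was therefore the only one of those planned that was run, and the cold response within a genotype, the genotype by cold interaction and the overlap of cold-called genes were not computed. The plan was to fit all 18 libraries together; with 6 libraries the fit held 2 groups and 4 residual degrees of freedom.

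The values are FPKM (fragments scaled by transcript length and by library size) per gene, deposited by the authors as a table of 33557 genes with 1 column per library. Reads were processed with TopHat2 and Cufflinks on the TAIR10 genome, per the submitters' processing notes; versions, filters, strand setting and the handling of reads that match several genes are not given in the sources used here. RNA was extracted with Trizol and DNase-treated before Illumina library construction, per the labels' protocols, which do not say whether RNA was selected by poly(A) tail. Column names gave the genotype and the time but numbered libraries from 0 to 2, where the sample titles count from 1 to 3, so libraries carry no replicate number of the titles here and are called a, b and c in the order of the table. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples.

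FPKM holds no total count. In genes with few fragments, values step by what 1 fragment is worth, and the commonest ratio between libraries in genes under 0.6 FPKM gave relative depths. Taking the shallowest library, WT a, as 1, depth was 1.43 in WT b, 1.24 in WT c, and 1.22, 1.23 and 1.01 in stch4-1 a, b and c. An exact 0 can be a failed estimate in such a table, so a gene with only zeros in a group is described as listed at 0.

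Gene identifiers were those of the table. Symbols, product descriptions, exon lengths and the order of genes came from the RefSeq annotation of assembly TAIR10.1, in which 32810 identifiers were found and 32802 had an exon length; no coordinates of it are given, since the deposited table was made on TAIR10. Joins used Python 3.11.15 with pandas 2.3.3.

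Genes with FPKM of 1 or more in at least 3 of the 6 libraries were tested, 19289 in all. Values were taken as log2(FPKM + 1), and fold changes are on that scale, which understates the change of low genes. limma 3.58.1 in R 4.3.3 fitted the 2 group means, with eBayes moderation that follows the intensity trend, 2-sided tests and Benjamini-Hochberg adjustment over all genes tested; genes at an adjusted p under 0.05 were called. Errors are SDs over 3 libraries. The 28 gene lists, with 612 listed members besides the plastid and mitochondrial genes taken by identifier prefix, were written before the data were examined; GOLS3 and RAP2.1 each stand in a pair of lists. Lists with at least 3 tested members were tested with limma's camera, at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists.

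Genes named in the text followed a rule set before the data were examined: REIL2 and REIL1; CBF1, CBF2, CBF3, COR15A, COR15B, COR47, RD29A, KIN1 and GOLS3; the 6 largest increases and the 6 largest decreases among called genes with an absolute log2 fold change of at least 1, a mean of at least 5 FPKM in the higher group and no overlap between groups; the 2 called members furthest in the direction of each called list; and the highest and lowest called member of any other list with at least 5 called. A gene named outside the rule is said to be so where it appears.

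The fit was tested on simulated data for this comparison, with 200 of 19289 genes changed. It recovered 61% of genes changed by 0.5 and 90% of those changed by 1 on the log2 scale, and 7.93% of its calls were false. In the real comparison 32.6% of tested genes were called, far more than were changed here, so these shares need not carry over. In a simulated list test, a list of 30 genes shifted by 0.3 was called and 0 of 30 unshifted lists were. Genes were simulated independently, so this does not show how the list test behaves when members correlate. In a simulated trend with length over 19153 genes, false calls fell from 354 to 13 on its removal, and the share of truly changed genes recovered fell from 84.8% to 77.2%. The planted trend itself adds calls, so the share before removal is not a trend-free baseline. Without a trend the shares were the 61% and 90% given above.

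Alternatives set before the data were examined were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, median-ratio rescaling, quantile normalization, eBayes without the trend, each library left out in turn, a call that also needs an absolute log2 fold change of 1, camera with an estimated correlation, and fry. Alternatives chosen after seeing the data were removal of each library's trend with exon length or with GC content, by lowess with a span of 0.3, nuclear genes only with median-ratio rescaling, and the number in the column names as a replicate block, which leaves 2 residual degrees of freedom.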

Results

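The libraries came from WT and stch4-1 seedlings after 4 h at 4 °C, with 3 libraries per genotype. STCH4, also called REIL2, is a zinc-finger protein related to yeast Rei1, which acts in late maturation of the large ribosomal subunit. Summed FPKM lay between 878394 and 919309 in WT and between 947218 and 987059 in stch4-1. Relative depth ranged from 1 to 1.43, and the deepest and the shallowest library were both WT. Spearman correlations between libraries, across genes, were 0.986 to 0.988 within genotypes and 0.983 to 0.985 between them.

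The comparison asks how the transcriptome of cold-treated seedlings differs when REIL2 is mutated. REIL2 (AT2G24500, chromosome 2) was measured first, as the mutated gene. Its FPKM was 33.8 ± 2.43 (SD, n = 3) in WT and 5.63 ± 0.184 (SD, n = 3) in stch4-1. That is a fall of 5.23 times on the log2(FPKM + 1) scale (limma log2 fold change -2.39, Benjamini-Hochberg adjusted p = 1.7e-06). The WT libraries read 31.2, 34.1 and 36.0 FPKM and the stch4-1 libraries 5.65, 5.44 and 5.804. Its paralogue REIL1 (AT4G31420) stood at 27.5 ± 0.914 in WT and 25.1 ± 1.54 in stch4-1 (limma log2 fold change -0.13, adjusted p = 0.108), and it passed the test only under quantile normalization (-0.17, adjusted p = 0.0425).

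In the cold, stch4-1 had more transcript of all 3 CBF genes, the transcription factors that switch on cold-regulated genes, and less of 8 of 14 of their targets. CBF1 rose from 309 ± 10.8 to 394 ± 16.4 FPKM, CBF2 from 876 ± 47.1 to 1137 ± 45.3 and CBF3 from 798 ± 74.5 to 997 ± 92.1. The target RD29A fell from 289 ± 0.511 to 178 ± 3.799 FPKM. Limma also called 12 of 21 salicylate defence genes, 18 of 21 jasmonate genes and 10 of 23 flavonoid and anthocyanin genes higher, and 9 of 11 iron deficiency genes lower.

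Of 19289 genes tested, limma called 3576 higher and 2704 lower in stch4-1. Most of these differences were small, with a median absolute log2 fold change of 0.31 among called genes. A change of at least 1 on the log2 scale was seen in 145 called genes, 87 higher and 58 lower. The groups did not overlap in 9221 genes, or 47.8%, where chance gives 10%. Under quantile normalization 2614 genes were called higher and 3108 lower, so the higher share moved from 56.9% to 45.7% of calls. Fold changes also fell with transcript length. With genes in 10 bins of length, the median log2 fold change was 0.18 in the shortest and -0.15 in the longest. Once that trend was removed, 4204 of the called genes remained called in the same direction.

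**Figure D1:**
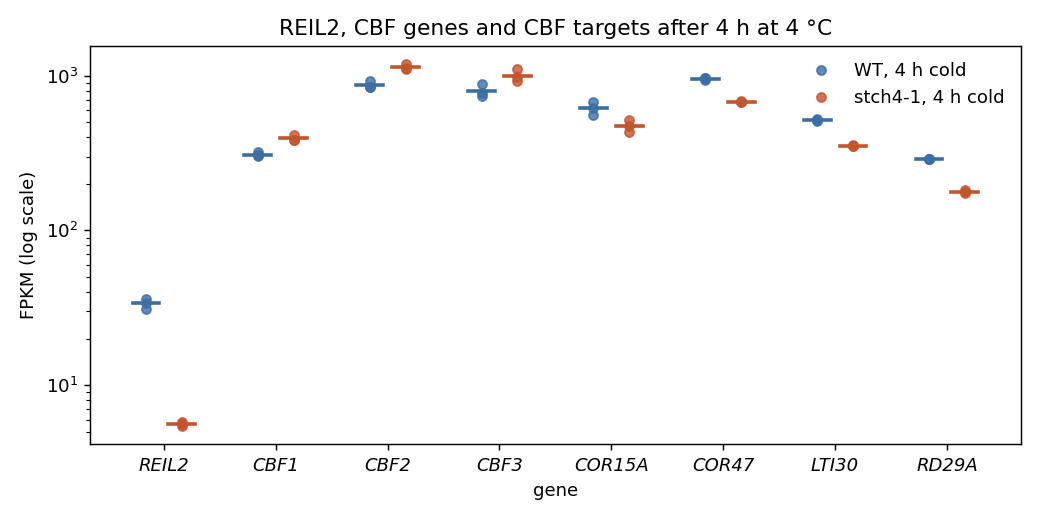
FPKM (log axis) of REIL2, 3 CBF genes and 4 CBF targets in each of the 3 WT and 3 stch4-1 libraries after 4 h at 4 °C. Points are libraries and bars are group means, and REIL2 sits between 5.44 and 5.804 in stch4-1 and between 31.2 and 36.0 in WT.

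Among the CBF genes, 3 of 3 were called higher, also when adjusted over the list alone. Camera called the list (adjusted p = 0.0123), and its adjusted p = 0.292 with an estimated correlation. That estimate was 0.94, far above the preset 0.01, so the call at the preset treats 3 correlated genes as nearly independent. CBF1 changed by a log2 fold of 0.35 (limma adjusted p = 0.00091), CBF2 by 0.38 (limma adjusted p = 0.0012) and CBF3 by 0.32 (limma adjusted p = 0.0199). Under quantile normalization the list median went from 0.35 to 0.18, with CBF1 at 0.18 and CBF2 at 0.21, and the CBF3 call was lost (0.17, adjusted p = 0.0854). The CBF3 call was also lost without WT a (adjusted p = 0.0601), WT c (adjusted p = 0.0691) or stch4-1 a (adjusted p = 0.0520). After removal of the length trend CBF2 stood at 0.24.

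Of 14 CBF targets, 8 fell and 0 rose, also when adjusted over the list alone, with a median log2 fold change of -0.27. Camera called the targets lower (adjusted p = 1.8e-05), and their adjusted p = 0.0831 with an estimated correlation. RD29A fell by 0.70 on the log2 scale (limma adjusted p = 1.0e-05). LTI30, a dehydrin, fell from 517 ± 9.03 to 353 ± 3.62 FPKM (limma adjusted p = 3.5e-05). COR47 fell from 957 ± 17.5 to 680 ± 5.96 (limma adjusted p = 6.5e-05) and COR15A from 620 ± 58.4 to 473 ± 42.6 (limma adjusted p = 0.0096). COR15B (480 ± 23.7 and 455 ± 6.66), KIN1 (163 ± 23.8 and 134 ± 26.8) and GOLS3 (57.5 ± 2.202 and 53.0 ± 2.26) did not pass. Under quantile normalization these 3 passed as lower (adjusted p from 0.0033 to 0.0462). The KIN1 log2 fold change of -0.29 became -0.44 without stch4-1 c, where it passed (adjusted p = 0.0372), -0.15 without stch4-1 b (adjusted p = 0.421) and -0.18 without WT b (adjusted p = 0.388).

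Transcription factors induced early in cold beside the CBFs had 8 of 18 members higher and 1 lower, or 10 and 1 when adjusted over the list alone, with a median of 0.21, or 0.13 under quantile normalization. For these factors camera gave adjusted p = 0.0043, and adjusted p = 0.292 with an estimated correlation. ERF6 rose from 49.4 ± 3.41 to 76.4 ± 3.51 FPKM and ZAT12 from 172 ± 8.41 to 262 ± 8.93. Regulators of the CBF genes had 2 of 14 members higher and 3 lower, also when adjusted over the list alone. As a list these regulators did not shift (camera adjusted p = 0.741), with a median of -0.01 and a mean of 0.02. MYB15, a repressor of CBF genes, rose from 6.39 ± 0.704 to 10.2 ± 0.586 FPKM. PIF7, a phytochrome-interacting factor, fell from 27.3 ± 1.56 to 20.5 ± 0.296.

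Clock genes had 14 of 26 members lower and 4 higher, also when adjusted over the list alone, with a median log2 fold change of -0.16. That median was -0.27 under quantile normalization and -0.09 after removal of the length trend. For the clock list camera gave adjusted p = 0.0008, and adjusted p = 0.108 with an estimated correlation. GIGANTEA (GI) fell from 38.1 ± 0.423 to 23.8 ± 0.584 FPKM and COR28, which links cold and the clock, from 57.5 ± 2.03 to 37.5 ± 1.09. In starch and sugar metabolism 8 of 18 genes fell and 3 rose, also when adjusted over the list alone, with a median of -0.10, or -0.17 under quantile normalization. For this list camera gave adjusted p = 0.0341, and adjusted p = 0.138 with an estimated correlation. The alpha-amylase AMY3 fell from 24.1 ± 0.801 to 16.01 ± 0.591 FPKM and the glucan phosphorylase PHS2 from 74.4 ± 1.18 to 50.5 ± 1.04. The starch list was no longer called without WT b (adjusted p = 0.0638) or stch4-1 b (adjusted p = 0.0530). Neither was it called after removal of the length trend (median of -0.01, adjusted p = 0.796) or the GC trend (adjusted p = 0.132).

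Ribosome biogenesis factors had 16 of 50 members lower and 2 higher, or 17 and 2 when adjusted over the list alone, with a median log2 fold change of -0.11. For these factors the camera adjusted p was 1.8e-05, and adjusted p = 0.105 with an estimated correlation. The helicase RH29 fell from 11.8 ± 0.528 to 8.21 ± 0.372 FPKM and RRP5, a factor of pre-rRNA processing, from 9.95 ± 0.110 to 6.91 ± 0.115. The list of cytosolic ribosomal protein genes, which does not hold the whole family, had 68 of 148 members higher and 1 lower, or 76 and 2 when adjusted over the list alone. AT3G08520, an L41 gene outside the list and outside the naming rule, went the other way. It lay between 22759 and 27634 FPKM in WT and between 6229 and 17686 in stch4-1. The median of the listed ribosomal protein genes, 0.13 (camera adjusted p = 3.9e-08, and adjusted p = 0.123 with an estimated correlation), turned to -0.02 under quantile normalization. After removal of the length trend the median of this list was 0.01 and it was not called (adjusted p = 0.845). RPS29A rose from 143 ± 8.90 to 193 ± 12.4 FPKM. RPS23A, at 2.06 ± 0.655 in WT and 3.55 ± 0.283 in stch4-1, was called higher, but not without stch4-1 a (adjusted p = 0.0665), without stch4-1 b (adjusted p = 0.0601) or after removal of the length trend (adjusted p = 0.108).

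Photosynthesis genes had 17 of 51 members higher and 0 lower, or 18 and 0 when adjusted over the list alone. Their median of 0.17 (camera adjusted p = 4.1e-05, and adjusted p = 0.492 with an estimated correlation) turned to -0.03 under quantile normalization. It was 0.08 after removal of the length trend and 0.09 without stch4-1 c. Plastocyanin PETE1 rose from 129 ± 5.15 to 170 ± 9.33 FPKM. PSBR of photosystem II stood at 4079 ± 618 in WT and 5627 ± 964 in stch4-1 (limma adjusted p = 0.0372). It was not called without WT a, WT c, stch4-1 a or stch4-1 c, without the filter, without the eBayes trend, under quantile normalization or after removal of the length trend (adjusted p from 0.0623 to 0.161).

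Salicylate defence genes had 12 of 21 members higher and 0 lower, or 15 and 0 when adjusted over the list alone, with a median log2 fold change of 0.50. The median was 0.27 over genes with a mean of at least 5 FPKM and 0.32 after removal of the length trend. For this defence list camera gave adjusted p = 1.1e-06, and adjusted p = 0.0596 with an estimated correlation. PR1, a secreted defence protein, rose from 70.7 ± 3.40 to 203 ± 19.6 FPKM, 2.84 times on the log2(FPKM + 1) scale (limma adjusted p = 1.1e-05). WRKY38 rose from 2.72 ± 0.271 to 6.998 ± 0.505. Jasmonate genes had 18 of 21 members higher and 0 lower, also when adjusted over the list alone, with a median log2 fold change of 0.37. For jasmonate genes camera gave adjusted p = 1.2e-08, and adjusted p = 0.0596 with an estimated correlation. The defensin PDF1.2 rose from 33.5 ± 3.85 to 69.8 ± 3.64 FPKM and the storage protein VSP2 from 99.96 ± 1.97 to 199 ± 7.21. Flavonoid and anthocyanin genes had 10 of 23 members higher and 0 lower, also when adjusted over the list alone, with a median of 0.22, or 0.08 under quantile normalization. For flavonoid genes camera gave adjusted p = 0.00015, and adjusted p = 0.0708 with an estimated correlation. The estimates were -0.042 for salicylate, -0.005 for jasmonate and -0.023 for flavonoid genes, all under the preset 0.01. A higher correlation between members therefore does not account for the loss of these list calls. Fry called the salicylate (adjusted p = 1.4e-05), jasmonate (adjusted p = 4.2e-05) and flavonoid lists (adjusted p = 9.6e-05). Unlike camera, fry does not compare a list with the other genes, and 32.6% of all tested genes were called. It also called the heat shock, glucosinolate and cell cycle lists, which camera did not, so its calls do not set these lists apart from other genes. DFR, which commits flavonoids to anthocyanin, rose from 62.9 ± 1.33 to 136 ± 0.741 FPKM and the anthocyanin glycosyltransferase UF3GT from 8.97 ± 0.542 to 18.6 ± 1.08.

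Iron deficiency genes had 9 of 11 members lower and 0 higher, or 10 and 0 when adjusted over the list alone, with a median log2 fold change of -0.79. For iron genes camera gave adjusted p = 8.2e-08, and adjusted p = 0.0615 with an estimated correlation. The iron transporter IRT1 fell from 9.62 ± 0.131 to 1.68 ± 0.231 FPKM (limma log2 fold change -1.99, adjusted p = 8.3e-06). The peptide gene IMA1 fell from 12.2 ± 2.24 to 2.89 ± 1.41 (limma log2 fold change -1.83, adjusted p = 0.0021). In these whole seedlings 10 of 16 root markers were also called lower. Whether a smaller share of root lowered the iron genes was not tested. Phosphate starvation genes had 11 of 15 members higher and 1 lower, or 12 and 1 when adjusted over the list alone, with a median of 0.28. For phosphate genes camera gave adjusted p = 2.2e-05, and adjusted p = 0.0888 with an estimated correlation. The noncoding RNAs IPS1 and AT4 rose from 185 ± 16.3 to 298 ± 5.16 and from 746 ± 36.0 to 1112 ± 71.5 FPKM.

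Of 16 root markers tested, 10 were lower and 0 higher, or 11 and 0 when adjusted over the list alone, with a median log2 fold change of -0.30, or -0.20 without the filter. For root markers camera gave adjusted p = 0.00027, and adjusted p = 0.123 with an estimated correlation. PRP3, a wall protein of root hairs, fell from 54.1 ± 1.98 to 33.1 ± 2.14 FPKM and the marneral synthase gene MRN1 from 5.36 ± 0.607 to 2.94 ± 0.145. Stomatal markers had 2 of 6 members higher and 1 lower, also when adjusted over the list alone. As a list they did not shift (camera adjusted p = 0.742), with a median of 0.04 and a mean of -0.02. Of 9 flower markers 2 were tested, of 10 seed markers 1, and of 4 nuclear rRNA genes 0, which is too few for a list test.

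Auxin response genes had 7 of 19 members higher and 0 lower, also when adjusted over the list alone, with a median log2 fold change of 0.18, or 0.12 without the filter. For auxin genes camera gave adjusted p = 0.0185, and adjusted p = 0.123 with an estimated correlation. SAUR21, which has near-identical copies and so an uncertain value, rose by a log2 fold of 0.74, and SAUR9 by 0.69. The auxin list was not called after removal of the length trend (median of 0.07, adjusted p = 0.217) or the GC trend (median of 0.06, adjusted p = 0.132). Genes of protein folding in the endoplasmic reticulum were higher in 5 of 5 tested members, also when adjusted over the list alone, with a median of 0.18, or 0.09 under quantile normalization. For protein folding camera gave adjusted p = 0.0056, and adjusted p = 0.123 with an estimated correlation. BZIP60 rose from 53.5 ± 2.17 to 64.2 ± 1.92 FPKM and SDF2 from 36.7 ± 2.05 to 43.8 ± 1.77.

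Lists without a call held members in both directions. Cell cycle genes had 6 of 22 lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.0571, and 0.0490 without WT c). MCM3, of the replicative helicase, fell from 7.86 ± 0.229 to 6.03 ± 0.496 FPKM. CYCD3-1, with a log2 fold change of 0.20 (limma adjusted p = 0.0248), was not called without WT b, WT c, stch4-1 a or stch4-1 b (adjusted p from 0.0569 to 0.0825). Heat shock genes had 4 of 14 higher and 2 lower, or 5 and 2 when adjusted over the list alone (camera adjusted p = 0.481). MBF1C rose from 9.14 ± 1.54 to 15.9 ± 2.26 FPKM and HSP18.2 fell from 8.10 ± 0.2995 to 5.03 ± 0.843. Abscisic acid and osmotic stress genes had 6 of 13 higher and 2 lower, or 6 and 3 when adjusted over the list alone (camera adjusted p = 0.334). RAB18 rose from 19.1 ± 2.15 to 29.2 ± 4.70 FPKM and ABF3 fell from 54.9 ± 2.72 to 45.9 ± 1.32. Aliphatic glucosinolate genes had 4 of 15 higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.479). BCAT4 rose from 313 ± 4.65 to 387 ± 7.70 FPKM and BAT5 fell from 86.3 ± 3.11 to 68.4 ± 2.43. Expansin and XTH genes of wall loosening had 5 of 21 higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.742). XTH22 rose from 128 ± 5.28 to 176 ± 9.15 FPKM and XTH17 fell from 22.3 ± 0.570 to 14.8 ± 0.502.

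**Figure D2:**
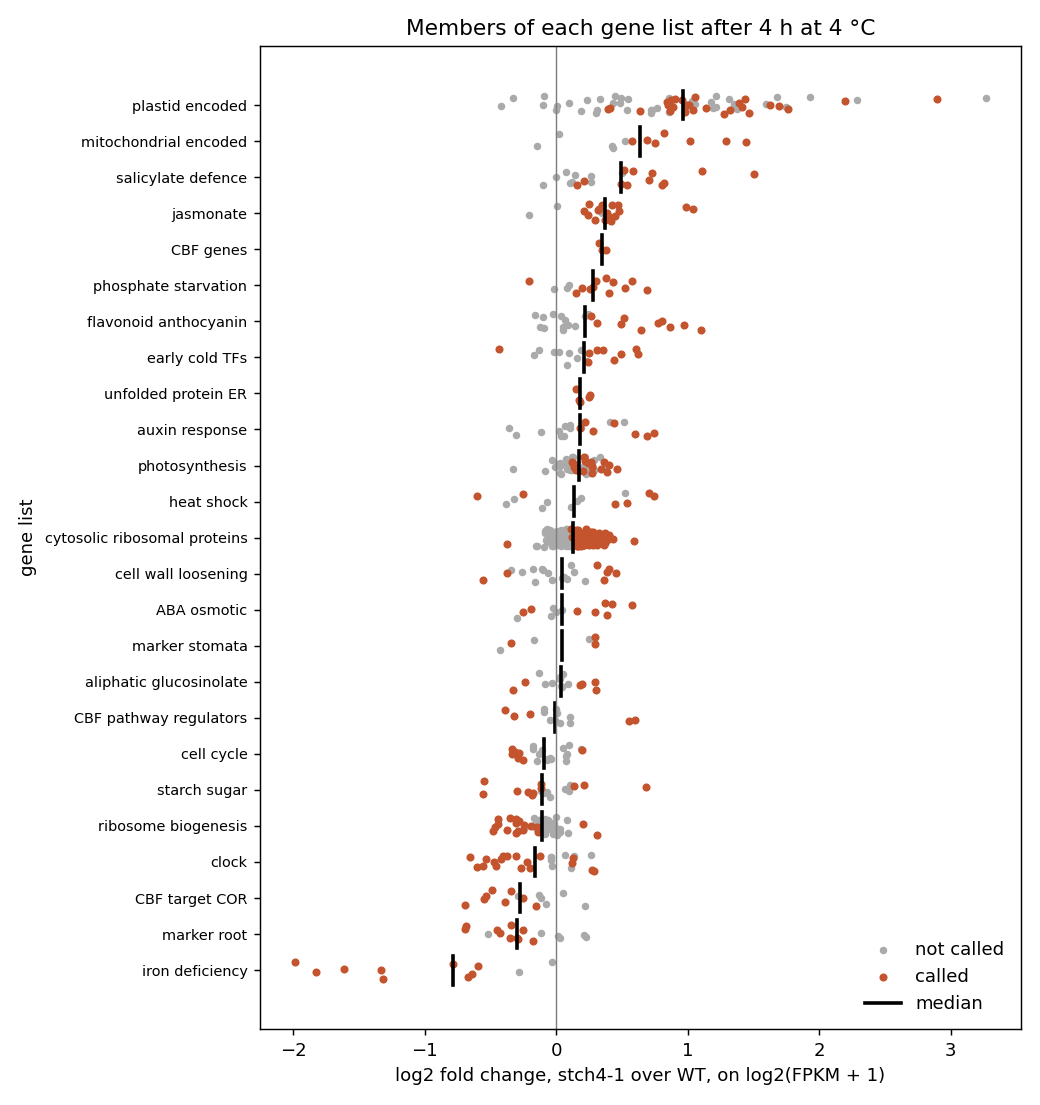
log2 fold change (stch4-1 over WT, horizontal axis) of each tested member of each gene list (vertical axis) after 4 h at 4 °C, on the log2(FPKM + 1) scale, with called members in orange, others in grey and list medians as black bars. Iron deficiency genes have the lowest median (-0.79) and plastid-encoded genes the highest (0.97).

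Summed FPKM of plastid-encoded genes was 1635, 334 and 508 in the WT libraries and 999, 1621 and 1408 in stch4-1, ranges that overlapped. Summed FPKM of mitochondrial genes was 79.5, 30.8 and 65.6 in WT and 102, 130 and 145 in stch4-1, ranges that did not. Of 68 plastid-encoded genes tested, 27 were higher and 0 lower, or 37 and 0 when adjusted over the list alone, with a median log2 fold change of 0.97, or 0.63 without WT b. For plastid genes camera gave adjusted p = 2.0e-07, and adjusted p = 0.354 with an estimated correlation. Of 146 mitochondrial genes in the table only 12 passed the filter and were tested, with 7 higher and 0 lower, also when adjusted over the list alone. Their median of 0.63 became 1.21 with a pseudocount of 0.1 and 0.17 without the filter. For mitochondrial genes camera gave adjusted p = 0.0086, and adjusted p = 0.285 with an estimated correlation. ATCG00710 rose from 1.02 ± 0.898 to 13.2 ± 4.27 FPKM, ATCG00905 from 1.43 ± 0.975 to 6.89 ± 0.948 and ATMG01080 from 1.25 ± 0.277 to 5.23 ± 1.57. ATCG00020, at 79.2 ± 56.6 in WT and 287 ± 58.8 in stch4-1, was not called without stch4-1 a, b or c or without the filter (adjusted p from 0.0512 to 0.0694). ATMG00030, at 35.3 ± 17.9 and 79.5 ± 15.3, was not called in these fits or without the eBayes trend (adjusted p from 0.0571 to 0.0938).

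The largest decreases, besides REIL2, included AT4G22485, a lipid-transfer protein gene, which fell from 48.4 ± 7.83 to 7.50 ± 3.08 FPKM (limma log2 fold change -2.59). AT1G52820, an oxygenase gene, fell from 9.56 ± 0.482 to 0.878 ± 0.243 (log2 fold change -2.50). The extensin genes AT1G23720 and EXT13 fell from 59.5 ± 6.81 to 12.8 ± 0.901 (log2 fold change -2.13) and from 51.0 ± 3.13 to 11.1 ± 0.619 (log2 fold change -2.11). SAMDC (AT3G02470), a polyamine synthesis gene, read 31.2, 118 and 39.3 FPKM in WT and 10.2, 13.5 and 11.1 in stch4-1, and its log2 fold change of -2.10 became -1.53 without WT b. The largest increases included AT5G41109, a gene model of 141 nt in TAIR10.1, which was listed at 0 in all 3 WT libraries and at 9.53, 9.14 and 11.02 FPKM in stch4-1. AT5G44575 rose from 7.56 ± 1.57 to 27.8 ± 2.48 FPKM and the defensin gene PDF1.2b from 8.71 ± 4.88 to 29.3 ± 4.27, beside 3 plastid genes given above. Extensin and defensin genes have close copies, so the division of reads among them is uncertain.

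**Figure D3:**
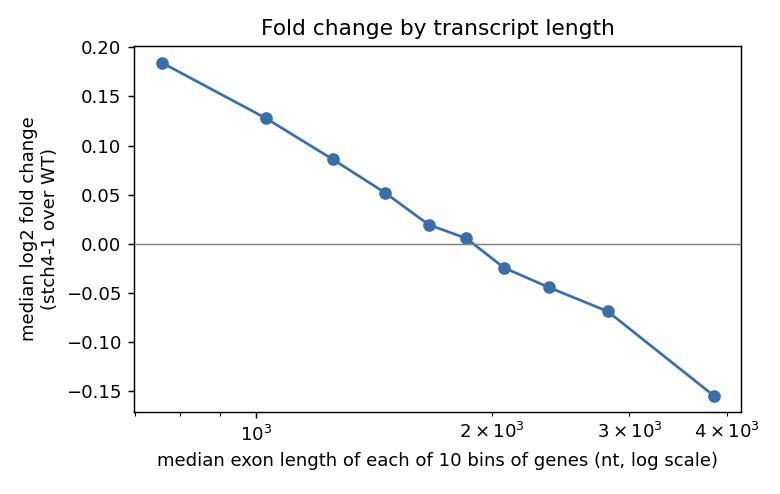
Median log2 fold change (stch4-1 over WT, vertical axis) in each of 10 bins of the tested genes, against the median exon length of the bin (nt, log axis). The median falls from 0.18 in the shortest bin to -0.15 in the longest.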

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

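Trend removals, the nuclear-only fit and the replicate block were chosen after seeing the data. The REIL2 fall kept its direction and call in every alternative that gave it a value, and calls numbered 4484 to 6304 except where a log2 fold change of 1 was also required (145 genes, 87 higher and 58 lower). No named gene changed direction in any alternative. KIN1 and GOLS3 also passed after removal of the length trend (adjusted p = 0.0409 and 0.0386), and COR15B after removal of the GC trend (adjusted p = 0.01995). Columns of both genotypes end in 0, 1 or 2, numbers that the titles do not match. Deviations from the group means correlated at -0.0361, -0.135 and 0.0534 between libraries of those numbers, so they share only a number, and not every library correlated best with its own. With that number as a replicate block 5080 genes were called, and the starch list (adjusted p = 0.0516) and PSBR (adjusted p = 0.0765) were not. A fit of only the compared groups equals the fit made, the pooled-column alternatives did not apply, and FPKM holds no counts, so counting error in low genes was not estimated. Trend removals gave no value for the plastid and mitochondrial lists, for lack of exon lengths. The split by genotype called 6280 genes and the highest of the other splits 2; the real one was the 1 split of 10 with as many, and 10 splits are too few for a share under 0.05.

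With an estimated correlation, even one under 0.01, no list was called. Adjusted p was 0.0596 for jasmonate and salicylate, 0.0615 for iron, 0.0708 for flavonoids, 0.0831 for CBF targets and 0.0888 for phosphate. It was 0.105 for ribosome biogenesis, 0.108 for the clock, 0.123 for ribosomal proteins, auxin, folding and root markers and 0.138 for starch. It was 0.285 for mitochondrial, 0.292 for CBF genes and early factors, 0.354 for plastid and 0.492 for photosynthesis genes. By fry, adjusted p was 0.0962 for photosynthesis, 0.00094 for heat shock, 0.0221 for glucosinolate, 0.00058 for cell cycle and, in the other direction, 0.767 for CBF regulators. Quantile normalization changed the direction camera gave for ribosomal proteins (0.660), photosynthesis (0.394), glucosinolate (0.325), wall loosening (0.663) and stomata (0.994). Removal of the length trend left starch at 0.796, ribosomal proteins at 0.845 and auxin at 0.217, and changed the direction for CBF regulators (0.392) and wall loosening (0.706). Removal of the GC trend left starch at 0.132 and auxin at 0.132. Leaving out 1 library gave 0.0255 to 0.0638 for starch, 0.0490 to 0.0819 for cell cycle and 0.614 to 0.999 for CBF regulators. List medians also changed sign, with the direction by camera kept, for heat shock (0.13 to -0.04) and stomata (0.04 to -0.07) after removal of the length trend, for wall loosening (-0.01) and stomata (-0.05) after that of the GC trend, and for heat shock (-0.03) and stomata (-0.05) without stch4-1 c. AT5G41109, listed at 0 in WT, is given no fold change, since its value depends on the pseudocount. Among the other named genes called in the main fit, besides the CBF genes, some log2 fold changes moved by over 1.5 times. Under quantile normalization these were RPS29A (0.43 to 0.28), PETE1 (0.40 to 0.26), BCAT4 (0.30 to 0.14) and BZIP60 (0.26 to 0.17). After length-trend removal they were RRP5 (-0.47 to -0.23), RPS29A (0.19), RPS23A (0.59 to 0.38), PSBR (0.46 to 0.28), BZIP60 (0.17) and IPS1 (0.69 to 0.44). Without WT b they were ATCG00020 (2.2005 to 1.396) and ATMG00030 (1.29 to 0.77). Named genes not called in the main fit moved as well. Quantile normalization took COR15B from -0.08 to -0.26 and GOLS3 from -0.12 to -0.20. Length-trend removal took KIN1 from -0.29 to -0.46, and GC-trend removal took COR15B to -0.16. The cause of these losses and moves was not tested, and removal of a length trend by itself lowered recovery in the simulation.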

Other observations

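The tests of product families, of sequencing depth, of library preparation, of shared reads, of the extensin family against the root markers, of mitochondrial carry-over and of library totals were chosen after the results were seen. Product descriptions were grouped into 182 families of at least 10 tested genes, and each was tested for an excess of calls in either direction (1-sided Fisher's exact test, Benjamini-Hochberg adjusted over 364 tests). Of these tests 14 were called, and 2 of them also with calls made after removal of the length trend, which called 6 others. Members of a family are not independent replicates, so the p-values of these tests do not measure the spread between samples. The family furthest from the rest was the proline-rich extensins, wall glycoproteins, with 11 of 12 members lower in stch4-1 (adjusted p = 2.2e-06, and 2.8e-07 after removal of the trend). Among members named after their values were seen, AT2G43150 fell from 390 ± 23.7 to 153 ± 3.40 FPKM and AT3G28550 from 99.5 ± 7.56 to 27.9 ± 0.521. Berberine-bridge-like oxidases had 10 of 18 members higher (adjusted p = 0.0130, and 0.0042 after removal of the trend). They were led by AT1G26390, also named after its values were seen (2.32 ± 0.162 to 9.67 ± 0.341 FPKM). Excesses of higher calls in small nuclear ribonucleoproteins (13 of 22) and histones (15 of 29) had adjusted p = 0.0025 and 0.0038, and adjusted p = 1 for both after that removal. Called only after it were lower lipid-transfer proteins (24 of 57, adjusted p = 1.8e-06), dirigent proteins (12 of 19, adjusted p = 2.4e-05) and peroxidases (17 of 54, adjusted p = 0.0090), and higher peroxidases (18 of 54), leucine-rich receptor-like kinases (10 of 21) and TIR-NBS-LRR proteins (16 of 45), each at adjusted p = 0.0132.

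Fold changes fell with exon length, with a Spearman correlation of -0.37 across 19153 genes, which are not independent replicates. Sequencing depth is argued against: the shallowest libraries of the 2 genotypes, of nearly equal depth, had length slopes that differed by 0.142 per doubling of length. The correlation stayed at -0.36 over genes outside the ribosomal protein and photosynthesis lists and families, which argues against these genes as its source. Slopes were taken on each library's deviation from the mean of each gene over the 6 libraries. Their opposite signs follow from that centring, and only the differences between libraries carry meaning. They were 0.048 to 0.072 in WT and -0.069 to -0.053 in stch4-1, a gap of 0.101. RNA integrity or library preparation that differed by genotype therefore cannot be told apart from an effect of the mutation. A shift of short against long transcripts in the mutant stays open as an untested biological explanation.

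Of 16 root markers 10 were called lower in stch4-1, with a list call that was lost with an estimated correlation (adjusted p = 0.123), and of 12 extensins 11 were called lower. The length trend is argued against, since 100% of the root markers and extensins called lower were still called after its removal. Summed extensin FPKM was 855 ± 47.9 (SD, n = 3) in WT and 301 ± 8.88 (SD, n = 3) in stch4-1, a ratio of 0.352. The fall is thus not a mere redistribution of reads among these 12 copies. The family was picked for its lower members, so a lower sum was bound to follow. Reads shared with copies outside the family were not tested. A smaller share of root may have lowered the root markers: 5 root-hair markers had a median of 0.03 and 11 other root markers -0.34, which differ by 0.371 (2-sided exact permutation test, p = 0.0130). The test permuted marker genes, which are not independent replicates, so its p-value does not measure the spread between samples. The hair markers were not uniform, since PRP3 among them, at -0.70, was the lowest of all root markers. The difference was under the 0.5 set in advance to exclude a smaller share of root. For these markers a smaller share of root thus cannot be told apart from lower expression. The extensins had a median of -1.44, below the lowest root marker (difference of -0.743 on the log2 scale). That family was picked as the furthest from the rest, so the comparison cannot exclude a smaller share of root. Lower extensin expression in the mutant stays open.

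Plastid-encoded transcripts were called higher in stch4-1 as a list (camera adjusted p = 2.0e-07), but not with an estimated correlation (adjusted p = 0.354). Library totals are argued against as the cause, since they differed 1.075 times between the genotype means, and with libraries rescaled to equal summed FPKM the list stayed called at the preset correlation, its median between 0.529 (without WT b) and 1.07 (without stch4-1 a). Summed plastid FPKM varied 4.90 times within WT and the ranges of the genotypes overlapped, consistent with a variable carry-over of RNA without a poly(A) tail, if such RNA was selected against, which the sources used here do not say. Mitochondrial sums did not overlap (30.8 to 79.5 in WT and 102 to 145 in stch4-1), but their means differed 2.14 times where WT libraries alone differed 2.58 times, so for these transcripts such a carry-over cannot be told apart from a difference between genotypes. That difference stays open for both organelles.

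Among the 100 tested neighbours of REIL2 in the gene order of TAIR10.1, 6 were called with an absolute log2 fold change of at least 0.5, against a median of 5 over other windows of that size, 55.0% of which held fewer. Genes carried along with the mutated locus can thus neither be seen nor excluded.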
